A study of Homo sapiens with 3 samples.

How the data were processed

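RNA was measured by sequencing of messenger RNA in human melanoma cells. The series has 3 samples, and 2 of them have a file that was used here. These are titled A375, Prop and A375-VR, Prop, with 1 library each. The third, titled A375-VR, DMSO, was not analysed here. Groups were taken from the titles, and the other labels disagree with them. The extraction protocol given for each sample names A375-VR cells, kept for 24 h in DMSO or in propranolol at 20 µM, while the title and the cell line label of the first library name A375. The sample titled A375-VR, DMSO also has A375 as its cell line label. The difference between the libraries can therefore stand for the cell line, for the drug, or for both, and the files do not settle which. With 1 library per group, it can also stand for any other way in which the cultures or library preparations differed.

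Per the series design text, libraries were made with a stranded TruSeq mRNA kit, read as pairs of 150 bp on a HiSeq 2000 and aligned with TopHat 1.3.3 to GRCh37. The counting tool, the gene annotation, the filters and the use of strand in counting are not given in the sources used here. The deposited values are FPKM (reads or fragments per kilobase of gene, scaled to the library total), with 1 value per gene and library, zeros kept and no pseudocount. The files list the same 20344 genes by symbol and Entrez number, and no symbol is on more than 1 row. FPKM shares the scaling of each library over all genes, so a few abundant genes that differ shift all the others.

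From the deposited FPKM, log2(FPKM + 1) was taken, and the value of the library titled A375, Prop was subtracted from that of the library titled A375-VR, Prop. Genes with an FPKM of at least 1 in at least 1 library were kept, and a difference of at least 1 in size was called 2-fold. A difference on this scale understates the change of low genes. Folds are plain ratios of FPKM, without the pseudocount, so a low gene can have a fold over 2 and not count as 2-fold apart. With 1 library per group there is no replicate check, so no p-value is given and no test of a condition was possible. The design fixed 35 gene lists before the data were examined. For each, the median difference of its members past the filter was set against 10000 random lists of the same size, matched on mean level in 20 bins, and a list was called apart at a percentile of at most 2.5 or at least 97.5. This describes these libraries and not the conditions. Named genes were taken by a rule of 3 parts. The first part names genes tied to the series title, among them CDK11A, CDK11B, CCNL1, CCNL2, ADRB1, BRAF and CDKN1A. The second part takes the 12 largest differences in each direction among genes with FPKM of at least 5 in the higher library, leaving out short RNA genes and genes tied to sex. The third part takes up to 4 members of each described list with the largest difference in size. Some genes that the rule takes are not reported here. Other genes are named with a statement that they were chosen after their values were seen.

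The depth was worked out after the files were seen. FPKM values from whole reads are whole numbers divided by gene length and library total. Every gene in the files came out whole in both libraries within a relative tolerance of 1e-06. The length of each gene was chosen to make its reads whole, so this was built in and is not counted as evidence. The recovered lengths could have failed. With the totals used here, the longest was 46064 bp. With the totals multiplied by an arbitrary factor, 0% of 3000 genes had a length that short. The ratio of the totals follows from the files alone. Their common factor was chosen, among 12 multiples tried, as the one under which most gene lengths equal the exon lengths of GENCODE release 44 on GRCh37: 15.1% of 3000 sampled genes against 10.7% for the next multiple. The totals so found are 17811339 for the library titled A375, Prop and 16438482 for the library titled A375-VR, Prop, and whether they count reads or fragments is not known. Over all genes, 15.0% of the lengths were equal to the reference and 50.1% lay within 2% of it. The reads of a gene are the smallest whole numbers that give its FPKM, so true counts can be multiples of them. Intervals of folds are 95% exact Clopper-Pearson intervals on these reads. They can be too wide, cover counting error only, and compare 2 libraries and not conditions. No count model was run.

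Steps were tested on simulated data with counts drawn from the real means and totals. With no change, 4 of 10565 genes were 2-fold apart and 1 list was apart. Of 200 changed genes with FPKM of at least 5, 100% of those changed 3-fold were called 2-fold apart and 0% of those changed 1.5-fold. The list of G1/S genes lowered 1.5-fold lay at percentile 0. Simulated genes were drawn independently and unchanged ones differed by counting noise alone, so these calls were close to fixed beforehand. They check the steps and not the calls on the real libraries, whose genes differ more widely and are co-regulated. Reads were recovered exactly for 86.35% of 2000 simulated genes, and the recovered reads divided the true ones in 100%.

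The 10 alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter at FPKM 5, rescaling to a common sum of 1000000 (TPM), centring on the median ratio, a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed), the highest row per symbol, short RNA and mitochondrial genes left out, and random lists not matched on level. After the data were seen, 2 more were added: the counting interval of each fold, and removal of a trend on exon GC content and length. A further 3 subjects for gene lists were also chosen then and appear only among the other observations. Gene positions are those of GENCODE release 44 on GRCh37, where 94.4% of symbols were placed. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.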

Results

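Expression was compared between 2 RNA libraries of A375 melanoma cells, a human line with mutant BRAF. Both titles carry the word Prop, and the extraction protocol names propranolol, a blocker of beta-adrenergic receptors. The series title concerns this drug, resistance to the BRAF inhibitor vemurafenib, the kinase CDK11 and the cell cycle. The libraries are called here, after their titles, the A375 library (titled A375, Prop) and the A375-VR library (titled A375-VR, Prop). The labels disagree on the cells and treatment of the first, so a difference between the libraries can be one of cell line or of treatment. It can also be one of culture or library preparation. There was 1 library per group and no replicate check, and intervals given with a fold cover counting error only. Folds are plain ratios of FPKM, while 2-fold counts and differences are on the log2(FPKM + 1) scale. The totals by which the values were scaled were 17811339 in the A375 library and 16438482 in the A375-VR library. Genes past the filter had a median of 605 and 621 recovered reads. Mitochondrially encoded genes made up 7.87% and 8.11% of the FPKM sum, and the 10 most abundant genes 8.87% and 9.35%.

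The largest differences between the libraries were in genes of sterol and fatty acid synthesis, which were higher in the A375-VR library, and cell cycle genes were lower there. Of 10761 genes past the filter, 338 were at least 2-fold higher in the A375-VR library and 66 at least 2-fold lower, so that 83.7% of these were higher. The split and the counts depend on the settings: they were 281 against 95 (74.7% higher) after centring on the median ratio and 248 against 116 (68.1% higher) with the trimmed mean of log ratios. The counts were larger after rescaling to a common sum, at 624 against 104 (85.7% higher), and with a pseudocount of 0.1, at 689 against 140 (83.1% higher). The trimmed mean moved the median difference of all genes from 0.10 to -0.03, and small differences can be read relative to that shift. Across genes the libraries had a Pearson correlation of 0.964 and a Spearman correlation of 0.958, and genes are not independent replicates. Counting noise alone gave 4 genes 2-fold apart in simulated libraries. Of the 34 lists with a member past the filter, 13 stood apart upward and 4 downward. Lists of independently drawn genes would give 1.7. Genes of a list are co-regulated and some lists share members, so this number does not measure chance for these lists.

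**Figure D1:**
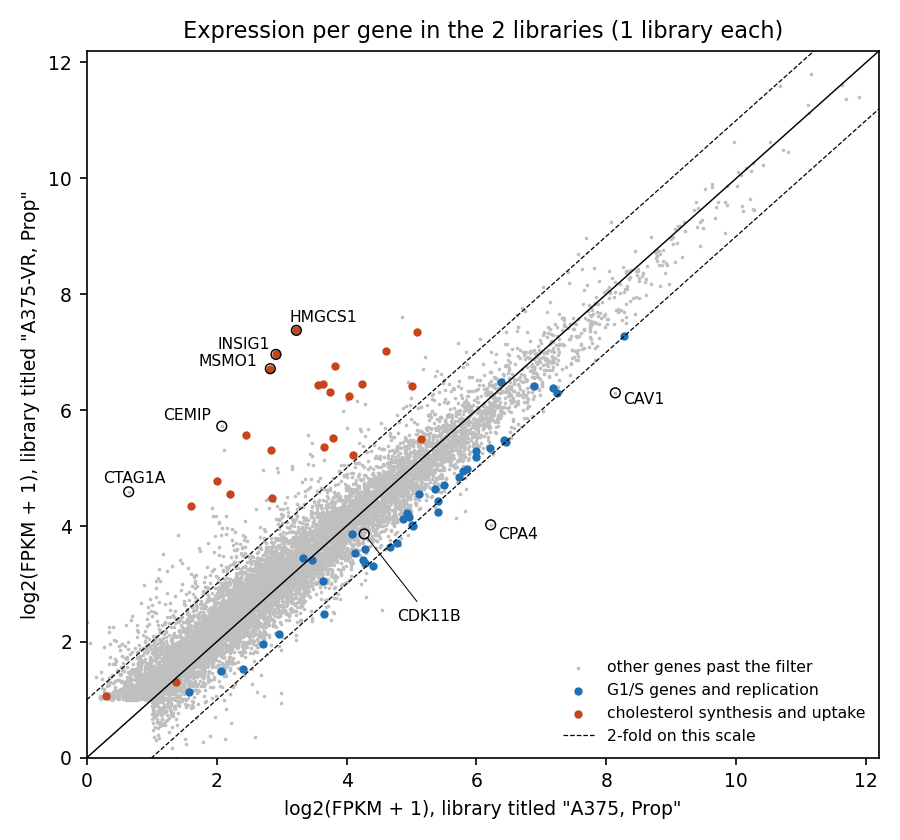
Each point is a gene past the filter, with log2(FPKM + 1) in the A375 library on the x axis and in the A375-VR library on the y axis. The solid line marks equal values, dashed lines mark 2-fold, coloured points are members of 2 gene lists and circled points are labelled genes. Of the 24 cholesterol genes, 21 lie on or above the upper dashed line, and 38 of the 40 G1/S genes lie below the solid line.

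Genes of cholesterol synthesis and uptake were higher in the A375-VR library almost throughout the list. Of 24 members past the filter, 21 were at least 2-fold higher and none was 2-fold lower, with a median difference of 2.38 at percentile 100 of matched random lists. HMGCS1 (Entrez 3157), which makes HMG-CoA for the mevalonate pathway, had 8.37 FPKM in the A375 library and 165 in the A375-VR library, a fold of 19.7 (18.3 to 21.3). It lies on chromosome 5 at 43287572 to 43313614 on the minus strand of GRCh37. INSIG1 (Entrez 3638), a membrane protein that holds the SREBP processing complex in the endoplasmic reticulum, had 6.54 and 124 FPKM, a fold of 18.9 (17.2 to 20.9), and lies on chromosome 7 at 155089486 to 155101945. MSMO1 (Entrez 6307), a sterol methyl oxidase, was 17.1-fold higher (14.5 to 20.2), and MVD, the decarboxylase of the mevalonate pathway, was 10.4-fold higher (9.34 to 11.6). DHCR7, SQLE and HSD17B7 were 7.89-fold, 7.60-fold and 8.71-fold higher. The 3 members under 2-fold with the pseudocount of 1 were PMVK, CYP51A1 and TM7SF2, named after their values were seen. CYP51A1 had 0.235 and 1.09 FPKM, a fold of 4.62 (2.605 to 8.74) from 15 and 64 recovered reads. TM7SF2 had 1.58 and 1.48 FPKM.

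Fatty acid genes shared this direction. All 15 members of the fatty acid synthesis list had a difference above 0, 10 were at least 2-fold higher, and the median was 1.17 (percentile 100). ACSS2 (Entrez 55902), which makes acetyl-CoA from acetate, had 3.35 and 38.5 FPKM, a fold of 11.5 (10.3 to 12.9). SCD (Entrez 6319), the desaturase that makes oleate, had 28.0 and 193 FPKM, a fold of 6.89 (6.62 to 7.18). PNPLA3 was 5.67-fold and LPIN1 3.89-fold higher.

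Lysosome genes were higher in the A375-VR library in 28 of 29 members, 6 of them at least 2-fold, with a median of 0.60 (percentile 100). CTSZ, a lysosomal cysteine protease, had 35.1 and 103 FPKM, and the sialidase NEU1 had 5.97 and 18.9. SQSTM1, an autophagy receptor counted in the lysosome and autophagy lists, had 51.3 and 142 FPKM, and CTSF was 2.74-fold higher. The autophagy list had a median of 0.34 (percentile 99.6), with 17 of 22 members above 0 and 4 at least 2-fold higher. WIPI1, a protein of forming autophagosomes, had 1.35 and 8.35 FPKM, a fold of 6.17 (4.87 to 7.90). MAP1LC3A was 2.41-fold and OPTN 2.34-fold higher.

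Genes of the G1/S transition and DNA replication were lower in the A375-VR library. Of 40 members past the filter, 38 had a difference below 0 and 8 were at least 2-fold lower, with a median of -0.82 (percentile 0). UHRF1, which maintains DNA methylation at replication, had 41.3 FPKM in the A375 library and 17.8 in the A375-VR library, a fold of 0.432 (0.406 to 0.458). PRIM1, a subunit of primase, had 11.6 and 4.62 FPKM, a fold of 0.399 (0.335 to 0.473). MCM5, part of the replicative helicase, had a fold of 0.453 (0.426 to 0.482). TYMS, thymidylate synthase, had a fold of 0.438 (0.289 to 0.652), and is uncertain because the opposite-strand gene ENOSF1 overlaps it. Mitotic genes differed less. Of 42 members of the G2/M list, 41 were below 0 and none was 2-fold lower, with a median of -0.49 (percentile 0). CDC20, an activator of the anaphase-promoting complex, had 225 and 116 FPKM, a fold of 0.515 (0.496 to 0.535). MAD2L1 had a fold of 0.589, BUB1B of 0.597 and BIRC5 of 0.604. SPC24, a kinetochore protein outside these lists, was among the 12 largest differences downward of genes with FPKM of at least 5 in the higher library, with 12.6 and 4.18 FPKM.

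**Figure D2:**
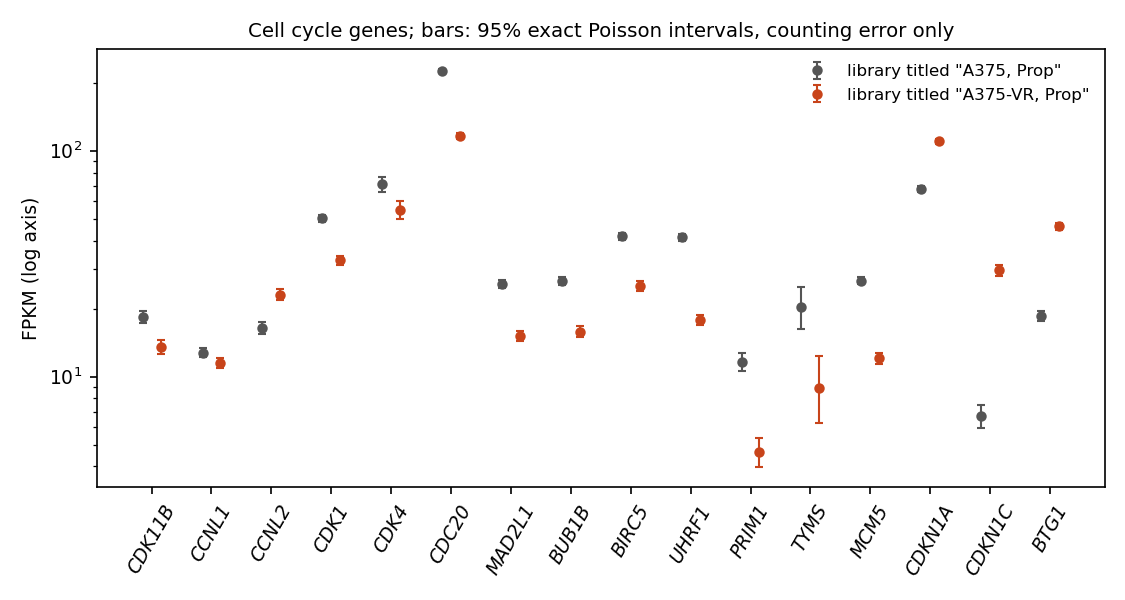
FPKM on a log axis of cell cycle genes in the A375 library (grey) and the A375-VR library (red), with 95% exact Poisson intervals that cover counting error only. Replication and mitotic genes such as UHRF1 and CDC20 lie lower in the A375-VR library, and CDKN1A, CDKN1C and BTG1 lie higher.

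CDK11, named in the series title, is encoded by the near-identical neighbours CDK11A and CDK11B, whose reads a counting tool can split or discard, so both values are uncertain. CDK11B (Entrez 984, chromosome 1 at 1570601 to 1590473, minus strand) had 18.3 FPKM in the A375 library and 13.6 in the A375-VR library, a fold of 0.739 (0.674 to 0.810). CDK11A (Entrez 728642, chromosome 1 at 1633818 to 1655796, minus strand) had 0.239 and 0.285 FPKM, from 20 and 22 recovered reads, and its fold of 1.19 (0.621 to 2.30) could not be told from 1 at this depth. The cyclin partners of CDK11 went apart: CCNL1 had a fold of 0.901 (0.844 to 0.963) and CCNL2 of 1.41 (1.295 to 1.53). As a list, CDK11 and cyclin L had a median of -0.14 (percentile 21.5; 3 members past the filter). Neither library is labelled as untreated, so these values hold no comparison with cells without the drug unless the protocol and not the title is right for one of them.

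Other cyclin-dependent kinases had a median of 0.01 (percentile 28.0), below 0 after centring and with the trimmed mean. CDK1 had a fold of 0.653 and CDK4 of 0.772, while CDK19 was 1.78-fold and CDK5 1.48-fold higher. The list of CDK inhibitors and p53 targets did not stand apart, with a median of 0.11 (percentile 71.8; -0.02 with the trimmed mean), 2 members at least 2-fold higher and 1 lower. CDKN1A (Entrez 1026), the inhibitor p21, had 67.8 and 110 FPKM, a fold of 1.62 (1.56 to 1.69). CDKN1C, the inhibitor p57, had 6.68 and 29.5 FPKM, a fold of 4.41 (3.88 to 5.03). The antiproliferative gene BTG1 was 2.49-fold higher, TP53INP1 3.28-fold higher, and GADD45B had a fold of 0.426. In the list of BCL2 family genes and caspases the median was 0.00 (percentile 27.9), and the pro-apoptotic gene BIK had 3.65 and 0.511 FPKM.

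Melanocyte lineage genes and MITF targets were higher in the A375-VR library, with a median of 0.62 (percentile 99.99), 10 of 12 members above 0 and 5 at least 2-fold higher. SOX10, a neural crest transcription factor, had 65.3 and 150 FPKM, a fold of 2.29 (2.21 to 2.38). ERBB3 was 3.58-fold, S100B 3.39-fold and GPNMB 2.77-fold higher. MITF itself, named after its values were seen, had 6.47 and 3.47 FPKM. A total of 15 of the 27 members of this list did not pass the filter. Genes tied to dedifferentiated or BRAF inhibitor-resistant melanoma went both ways and did not stand apart, with a median of 0.07 (percentile 50.7; -0.02 with the trimmed mean), 1 member at least 2-fold higher and 4 lower. CTGF, CYR61 and ANKRD1, targets of the YAP coactivator, had folds of 0.328 (0.2995 to 0.358), 0.326 (0.2998 to 0.354) and 0.169 (0.117 to 0.238), and the matrix gene TGFBI was 3.15-fold higher.

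Target genes of MAPK signalling had a median of 0.55 (percentile 100), with 19 of 23 above 0 and 3 at least 2-fold higher. DUSP4, an ERK phosphatase induced by the pathway, had 28.4 and 64.9 FPKM, and LIF, SPRY4 and PHLDA1 were 2.49-fold, 2.49-fold and 2.02-fold higher. The kinases themselves did not stand apart. BRAF (Entrez 673) had 0.8003 and 0.916 FPKM, a fold of 1.15 (0.983 to 1.33), not detectably different at this depth. RAF-MEK-ERK and PI3K-AKT components had a median of 0.20 (percentile 90.1), with PIK3CB, TSC1, MAPK3 and PIK3CA between 1.58-fold and 1.94-fold higher. The cAMP and CREB response list had a median of 0.55 (percentile 99.96), with 12 of 14 above 0, and the nuclear receptors NR4A1 and NR4A2 were 2.89-fold and 4.44-fold higher. Among adrenergic receptors and their transducers the median was 0.07 (percentile 31.0), below 0 after centring and with the trimmed mean. ADRB1 rested on 2 and 6 recovered reads, and its fold of 3.25 (0.581 to 32.9) could not be told from 1. GNAS, the stimulatory G protein, had 86.3 and 162 FPKM.

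**Figure D3:**
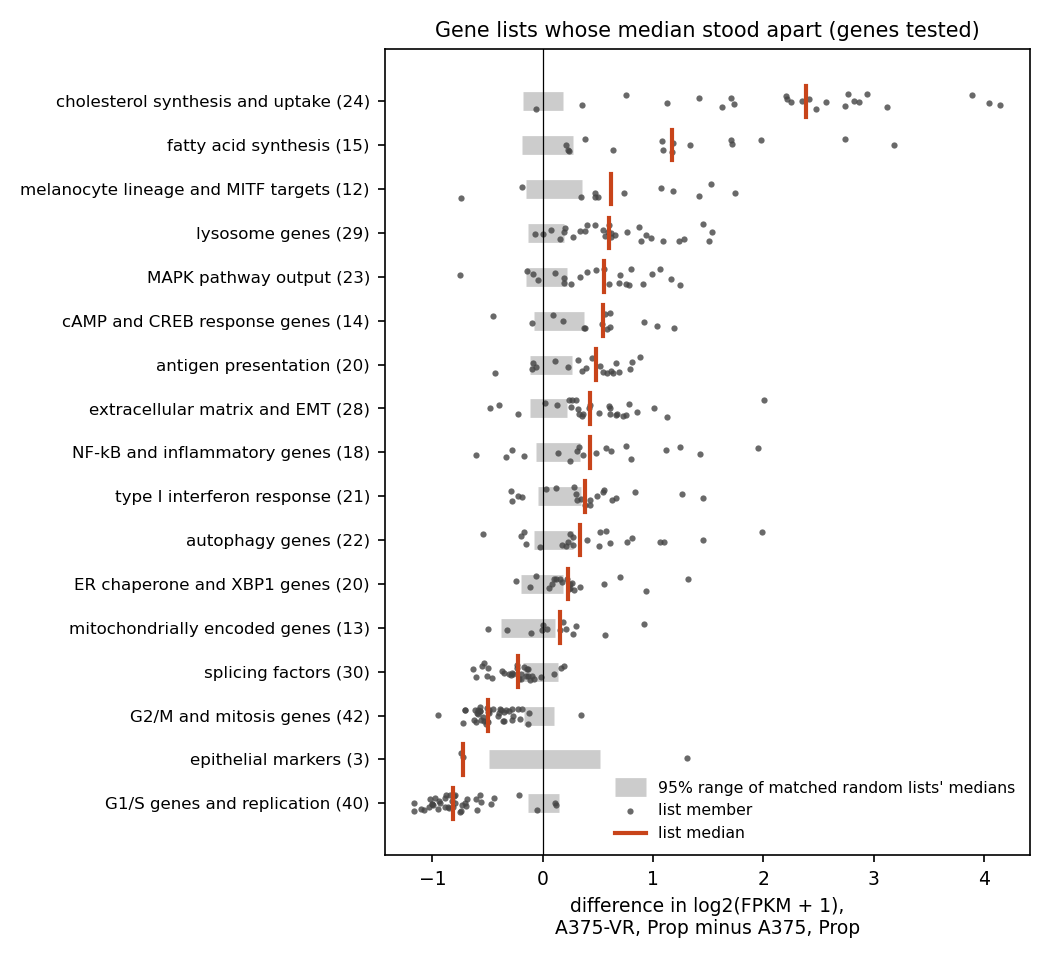
Difference in log2(FPKM + 1), A375-VR library minus A375 library, of the members (dots) of each gene list whose median (red bar) stood apart, with the 95% range of the medians of matched random lists in grey. The number of members past the filter stands beside each list; the medians run from 2.38 for cholesterol genes to -0.82 for G1/S genes.

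Immune and matrix lists stood apart upward by smaller medians. Antigen presentation genes had a median of 0.48 (percentile 99.99), with 16 of 20 above 0 and none 2-fold apart with the pseudocount of 1. HLA-B was 1.91-fold and CIITA 2.48-fold higher, and reads of HLA genes can be shared between paralogs. NF-kB and inflammatory genes had a median of 0.42 (percentile 99.7), and 4 of 18 were at least 2-fold higher. Of these the cytokine IL24 had 10.1 and 42.1 FPKM. Type I interferon response genes had a median of 0.38 (percentile 98.9) with 2 of 21 at least 2-fold higher, IFI35 at 2.93-fold and BST2 from 2 and 30 recovered reads. This list did not stand apart with the filter at FPKM 5 (percentile 97.45). For extracellular matrix and mesenchymal genes the median was 0.43 (percentile 100), with 25 of 28 above 0. ITGB3 was 6.68-fold (5.33 to 8.46) and the matrix protein gene SPARC 2.19-fold higher.

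Splicing factors were lower by a small amount in 27 of 30 members, none 2-fold, with a median of -0.22 (percentile 0.49). U2AF2, SRSF7, SRSF2 and SRRM1 had folds from 0.639 to 0.680. ER chaperone and XBP1 genes had a median of 0.23 (percentile 99.1), with DNAJB9 at 2.89-fold. The mitochondrially encoded list had a median of 0.16 (percentile 98.9; 0.01 with the trimmed mean) and its members went both ways, from a fold of 0.711 for MT-CO3 to 1.89 for MT-CO1. The last 2 lists lost their call with random lists not matched on level, and the mitochondrial list also with the trend on GC content and length removed. Epithelial markers had a median of -0.73 (percentile 0.18) over only 3 members, and did not stand apart without the filter. The keratin genes KRT8 and KRT18, which overlap on opposite strands, had folds of 0.592 and 0.597, and CLDN4 was 2.98-fold higher.

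No other list stood apart with the main settings. The medians were 0.05 for nuclear genes of oxidative phosphorylation (below 0 after centring and with the trimmed mean), -0.09 for ribosomal proteins, 0.01 for glycolysis and hypoxia genes (below 0 after centring and with the trimmed mean), -0.07 for ATF4 and CHOP stress genes and -0.05 for heat shock and NRF2 genes. Single members still differed, among them PFKFB4 at 3.62-fold and ALDOC at 3.58-fold in the glycolysis list, and HMOX1 at 2.29-fold in the NRF2 list. Replication-dependent histones had a median of 0.16 over 8 of 14 members. HIST1H2AC and HIST1H2BK had folds of 0.413 and 0.469, and copies of histone genes make these uncertain. Other members rested on few recovered reads, HIST2H2BE on 11 and 24 and HIST1H3H on 15 and 34. How well an mRNA library captures histone transcripts was not tested, so the list is not read as a measure of replication. With the filter at FPKM 5 the list turned direction and stood apart, at -0.45 (percentile 1.54). The list also holds H1F0, a histone gene not tied to replication and named after its values were seen, with a difference of 0.19. Drug efflux transporters had a median of 0.40 (percentile 93.0), with 7 of 7 above 0 and ABCC2 at 2.11-fold. As markers of other cell types, keratinocyte genes had a median of 0.31 over 4 members past the filter, fibroblast genes 0.32 over 2 and endothelial genes 0.20 over 4, and 0 of 14 leukocyte markers passed the filter.

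Among the 12 largest differences upward outside the lipid lists, CEMIP (Entrez 57214), a hyaluronan-binding protein, had 3.23 and 51.8 FPKM, a fold of 16.1 (14.6 to 17.7), and lies on chromosome 15 at 81071684 to 81244117. CTAG1A (Entrez 246100), a cancer-testis antigen gene on chromosome X at 153813397 to 153815075, had 0.565 and 23.1 FPKM, from 10 and 377 recovered reads, and is uncertain because CTAG1B is a near-identical copy. Among genes with FPKM of at least 5 in the higher library, the 12 largest differences downward were in KRTAP2-3, CPA4, MARCH4, PTX3, ANKRD1, CAV1, F3, CYR61, CTGF, KISS1, SERPINB7 and SPC24. CAV1 (Entrez 857), the main protein of caveolae, had 281 and 77.7 FPKM, a fold of 0.277 (0.268 to 0.285), and lies on chromosome 7 at 116165048 to 116201233. The carboxypeptidase gene CPA4 had 73.5 and 15.2 FPKM, a fold of 0.207 (0.193 to 0.222). F3, tissue factor, had a fold of 0.194 (0.142 to 0.262), PTX3 of 0.218 (0.1503 to 0.309) and MARCH4 of 0.132 (0.101 to 0.171). KRTAP2-3 rested on 78 and 4 recovered reads and has near-identical paralogs, so its value is uncertain.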

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

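The trend removal and the counting intervals were chosen after seeing the data. For results that moved, the cause was not tested unless it is given here. Counts of 2-fold genes grew with a pseudocount of 0.1, to 689 higher and 140 lower, and after rescaling to a common sum, to 624 higher and 104 lower; in each the pseudocount is small beside the values. The trimmed mean gave 116 lower. Without the filter the epithelial list had a median of 0 (percentile 37.6), from members near 0 FPKM. With the filter at FPKM 5 the histone list stood apart at -0.45 (percentile 1.54), and the interferon list ended just inside at 0.38 (percentile 97.45). With random lists not matched on level, the ER chaperone (0.23) and mitochondrial (0.16) lists no longer stood apart and the ribosomal list did (-0.09), by construction of the comparison. With the trend on GC content and length removed, the mitochondrial list was at 0.13 (percentile 96.9). The other 353 list medians under an alternative kept their call, and no list that stood apart changed sign. Part of this was fixed beforehand, since a scaling shifts a list and its matched random lists together. The mitochondrial list thus kept its call with the trimmed mean at a median of 0.01. Among single-gene values under an alternative, 1384 moved by at most 1.5-fold and 21 by more, all with another pseudocount or the common sum. Taking the highest row per symbol moved nothing, since no symbol was repeated. The fibroblast (2 members) and leukocyte (0) lists were not followed. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group has 1 library. Depth limits CDK11A and ADRB1, at 22 and 6 recovered reads or fewer.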

Other observations

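The tests of the GC content and length trend and of chromosome arms were set before their results were seen. All other tests in this part, their gene lists, and the division of the arms by interval were chosen after the values had been seen.

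The higher sterol genes were weighed first. A trend on exon GC content and length was argued against, since the list median was 2.36 after its removal. The lowest median under 4 scalings was 2.24. A scaling shifts all genes nearly alike, by 0.15 on the log2 scale with the trimmed mean. The outcome for so large a median was therefore close to fixed beforehand and is not counted as evidence. The 21 members at least 2-fold higher lie on 14 chromosomes, which argues against a gain of 1 or 2 chromosomes. A hypothesis of sterol depletion, which may also lower LXR targets, was left undecided by a list of 8 LXR targets: its median was 0.42, at percentile 97.8 of matched random lists and so on the opposite side, but its bootstrap interval of -0.03 to 0.73, added after the median was seen, reaches 0. That median is set by NR1H3 and NR1H2, the LXR receptors themselves, while the target MYLIP had a fold of 0.468 (0.346 to 0.628) and ABCG1, under the filter, had 10 and 0 recovered reads. The cell line and the drug stay open as sources, because the labels do not say which of them separates the libraries. So do differences of culture or library preparation, because each group has 1 library.

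The lower G1/S genes were weighed next. The median was -0.75 after removal of the GC content and length trend, so that trend does not account for the whole difference. It was -0.79 at its highest under 4 scalings, which is again not counted as evidence, since a scaling shifts all genes nearly alike. A hypothesis that the same share of cycling cells was lost in every phase stayed open. The G1/S median lay -0.32 from the G2/M median, outside the range of -0.14 to 0.14 from random divisions of the genes and so against an equal loss, but both medians had been seen before they were compared, co-regulated genes are not independent units, and residual expression outside the cycle may differ between the lists, so this does not exclude it. The cell line, the drug and differences of culture or library preparation stay open here too.

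The 2 libraries may come from cell populations with different copy number, as a long-selected derivative can. In 40 chromosome arms whose interval stayed within 0.2 the largest median shift, in 20p, was 0.10 (0.02 to 0.17), which argues against an arm-level change in most cells there. In 18p the median shift over 36 genes was -0.11, with an interval of -0.21 to -0.01 that excludes 0 and reaches 0.2 in size. Its mean shift of -0.10 lay within the range of -0.19 to 0.37 from random reassignments of genes to arms. A copy number change of 18p was therefore neither shown nor excluded. Intervals of other arms also excluded 0, among them 20p and 19p (-0.14 to -0.04), and none was corrected for the number of arms. A simulated change of 18p by the ratio of 4 to 3 copies gave a shift of 0.36 in size. Before the arms were divided, the test as first set had called copy number excluded as a whole, and the division was made because the interval of 18p did not allow that. That first test could also miss a gain. It asked for a mean shift outside the random range, whose upper end of 0.37 is above the simulated median shift of 0.36. Changes smaller than an arm, and a resistant line without arm-level changes, stay open, so this does not show that both libraries hold the same line.

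CTGF, CYR61, ANKRD1 and F3 were all lower in the A375-VR library, and a hypothesis is that YAP and TEAD targets may be lower as a whole. The first list held TEAD4 and AJUBA, already seen to be lower, and had a median of -0.23 (percentile 0.125). Without them, a removal made after all the members' values had been seen, the median of 17 genes was -0.19 (percentile 0.60), and without AXL as well it was -0.13 (percentile 1.82). Of the 17 genes, 10 were below 0 and 7 above, none was 2-fold lower, and the bootstrap interval of the median was -0.45 to 0.12, so the support is weak.

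CTAG1A and XAGE1A were higher in the A375-VR library, XAGE1A from 1.15 to 8.58 FPKM. The other 14 cancer-testis genes past the filter had a median of -0.10 (bootstrap interval -0.29 to 0.12) and none was 2-fold apart, which argues against a higher level of the class as a whole. XAGE1B, among these 14, had 1.35 and 1.29 FPKM. How reads were divided between XAGE1A and XAGE1B is not known, so the XAGE1A value is uncertain.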
